A study of Mus musculus with 6 samples.

How the data were processed

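Liver mRNA was measured in 6 libraries from mice fed a western diet for 20 weeks from an age of 8 weeks. The mice carried floxed Hkdc1 (flox) or a liver-specific Hkdc1 knockout (LKO). Per the labels' protocols, RNA was extracted with TRIzol, poly-A RNA was selected and libraries were made with an NEBNext Ultra kit. Whether each library came from a separate mouse is not stated, so p-values measure the spread between these samples, which may be technical.

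The authors deposited 1 table of 23036 genes with whole-number counts and FPKM for each library. Per the submitters' processing notes, the tools were fastp, HISAT, StringTie, Cufflinks and featureCounts, and the genome build was GRCm39. Their versions, their roles, the gene annotation and the strand setting are not given in the sources used here. The deposited counts are not normalized. The deposited FPKM values equal each count divided by 1 length per gene and by the sum of the library's counts, with a spread of at most 0.036% over 7260 genes that had at least 200 counts. Of the rows, 17199 were protein-coding, 5826 were lncRNA and 586 were 0 in every library. Gene symbols and coordinates (1-based) come from the deposited table. Reads shared by near-identical genes, such as the Mup, Cyp2c, Cyp3a and Sult2a families, can be split between the copies, and these genes are reported as uncertain. Overlapping genes and antisense pairs are uncertain too.

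The genotype field of the labels set the groups, 3 flox and 3 LKO libraries, numbered in accession order within each group. The title of the library labelled flox 3 names LKO, and the title of the library labelled LKO 1 names flox. The same comparison was therefore repeated on the 4 libraries whose title and genotype field agree (flox 1, flox 2, LKO 2 and LKO 3) and on the groups the titles name. Library names below always follow the genotype field. These choices, the tests, the 40 gene lists and the rule for naming genes were fixed before the data were examined.

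Counts were tested with edgeR 4.0.16 (glmQLFit and glmQLFTest, R 4.3.3) after filterByExpr (minimum count 10, minimum total 15) and TMM scaling, with Benjamini-Hochberg adjustment and a threshold of 0.05. Hkdc1 was kept in each fit whether or not it met the filter, and left out of counts of other genes. The standard error of a log2 fold change was taken as its size divided by the square root of F. Fold changes are LKO against flox throughout. CPM values use TMM scaling over all 6 libraries. Gene lists with at least 5 tested genes were tested with camera (limma 3.58.1, correlation 0.01) on voom values. They were tested again with an estimated correlation and with fry, whose PValue tests whether a list's genes move one way on balance. The mixed test of fry (PValue.Mixed) asks whether they change in either direction. Results given by fry are of its PValue unless the mixed test is named. Of 804 list entries, 777 matched by symbol, 9 by synonym and 18 did not match. Hkdc1 CPM was also compared with an exact two-sided permutation test. Intervals of counts are 95% exact Poisson intervals and cover counting error only.

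Named genes were Hkdc1, then up to 10 higher and 10 lower genes past the threshold. These had a mean of at least 1 CPM, non-overlapping groups and an official symbol, and were ranked by fold. A direction with fewer than 10 was filled with up to 5 genes of lowest unadjusted p. For each described list the 2 members of lowest p were added, and then the other hexokinase genes Hk1, Hk2 and Hk3. Some items that the rule names are not reported here. Genes outside this rule are said to be chosen after their values were seen.

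The total count per library was 16166515 to 17366295. A count of 3, used as the floor, corresponded to 0.173 to 0.186 CPM. No pair of libraries agreed within sampling noise: the chi-square per gene was 17.3 to 74.6. The edgeR test was tested on simulated data made from the real means and library sizes with 100 genes changed 2-fold and 100 changed 4-fold. It recovered 46% and 85% of them with the genotype-field groups, 40% and 76% with the 4 agreeing libraries, and 61% and 87% with the title groups. Of its 141, 132 and 162 calls in these simulations, 8, 13 and 13 were on unchanged genes, with 14311, 14626 and 14311 genes simulated. The simulated genes varied independently of each other, which real genes need not do.

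Alternatives were other size factors (median of ratios, upper quartile, library size alone), no filter or a mean of at least 1 CPM, leaving out the 20 most abundant genes, DESeq2 1.42.0, limma-voom and limma-trend on log2(FPKM + 1) and log2(FPKM + 0.1). Others were leaving out each library, another threshold, and fgsea 1.28.0 or fry for the lists. Running them on the 4 agreeing libraries and on the title groups, and leaving out genes at least 8 times higher in LKO 2 than in flox 1 to 3 and LKO 1, was added after the data were seen. Marker lists of adrenal cortex, adrenal medulla, brown fat, ovary, kidney and gut epithelium, and a camera test of the KEGG pathways named in the deposited table, were also added then, as was that pathway test without the genes high in LKO 2. Carry-over from LKO 2 into LKO 3 was tested first with Mup12 and, after that result was seen, with the shares of the marker lists.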

Results

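Bulk liver RNA was sequenced from female mice after 20 weeks of western diet, a high-fat, sugar-rich diet used to induce fatty liver disease. The comparison asks how loss of Hkdc1 in the liver alters gene expression during steatohepatitis (MASH). Hkdc1 encodes hexokinase domain containing 1, a member of the hexokinase family, whose members phosphorylate glucose. There were 3 libraries labelled flox and 3 labelled LKO by their genotype field. Total counts were 16913372, 16166515 and 16322690 in flox 1 to 3 and 17366295, 16420873 and 16734565 in LKO 1 to 3.

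Hkdc1 (ENSMUSG00000020080, GRCm39 chromosome 10, 62218916 to 62258270, minus strand) differed between libraries that share a genotype field. It had 49 counts in flox 1 (95% interval 36.3 to 64.8) and 22 in flox 2 (13.8 to 33.3). The library labelled flox 3, titled LKO, had 1 count (0.0253 to 5.57). The library labelled LKO 1, titled flox, had 10 counts (4.80 to 18.4). LKO 2 had 1 count (0.0253 to 5.57) and LKO 3 had 4 (1.09 to 10.2). The counts cover the whole gene, and the deleted part is not given in the sources used here. Grouped by the genotype field, Hkdc1 averaged 1.32 ± 1.24 CPM in flox and 0.302 ± 0.269 CPM in LKO (SD, n = 3 each, exact permutation p = 0.3, smallest possible 0.1). Its log2 fold change was -2.12 (SE 1.07, edgeR adjusted p = 0.571). In the 4 agreeing libraries it averaged 1.95 ± 0.830 CPM in flox and 0.157 ± 0.137 CPM in LKO (SD, n = 2 each, exact permutation p = 0.333, the smallest possible). There the log2 fold change was -3.59 (SE 0.75, edgeR adjusted p = 0.11). Grouped by the titles, the means were 1.496 ± 0.978 and 0.126 ± 0.110 CPM (SD, n = 3 each, exact permutation p = 0.1, the smallest possible), with a log2 fold change of -3.51 (SE 0.76, edgeR adjusted p = 0.108). Every direction drawn from the genotype field below therefore rests in part on flox 3, whose Hkdc1 level goes against that field, and on LKO 1, whose level lies under both agreeing flox libraries and above both agreeing LKO libraries.

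**Figure D1:**
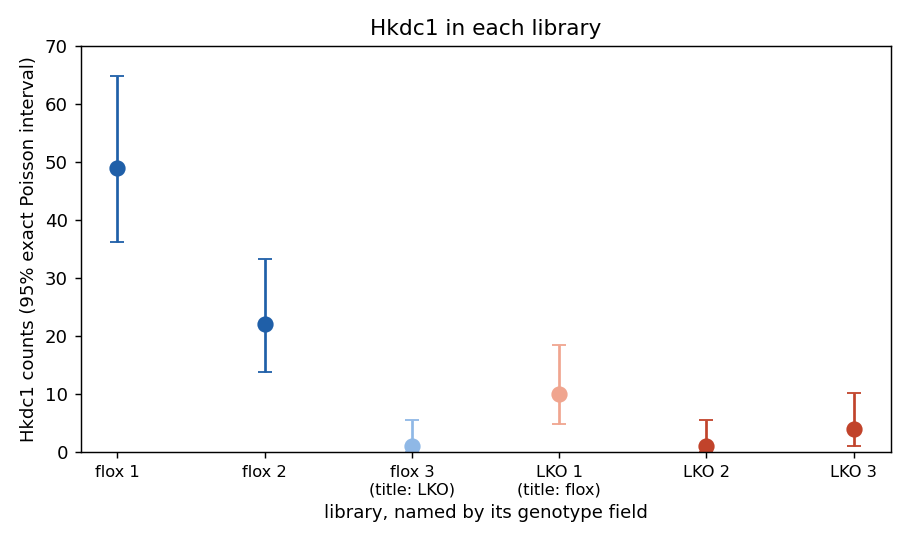
Hkdc1 counts (vertical axis) in each of the 6 libraries (horizontal axis, named by genotype field, with the title's genotype where it differs), with 95% exact Poisson intervals. The library labelled flox 3 had 1 count and the library labelled LKO 1 had 10.

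With the groups of the genotype field, no single gene passed the threshold, and the genes of lowest p included Gldc, Nr1d1 and Mki67. Gldc, the glycine decarboxylase of the mitochondrial glycine cleavage system, averaged 65.5 ± 4.36 CPM in the libraries labelled flox and 116 ± 1.29 CPM in those labelled LKO (SD, n = 3 each). Its log2 fold change was 0.82 (SE 0.10, edgeR adjusted p = 0.361). Nr1d1, a circadian repressor, had a log2 fold change of 0.78, and Pde9a, a cyclic GMP phosphodiesterase, of 1.04. Tuba4a, an alpha-tubulin, and the kinase gene Tnk2 had log2 fold changes of 0.87 and 0.55. In the other direction, Cobl, an actin nucleator, had a log2 fold change of -0.81, the kinase gene Map3k6 -1.24, the proliferation marker Mki67 -1.49, Snx10 -0.53 and Zbed6 -0.68. None of these 10 genes passed (edgeR adjusted p 0.361 to 0.554). Of 14310 genes tested by edgeR, 0 passed and 1267 (8.85%) had an unadjusted p under 0.05. DESeq2 called 35 genes, limma-voom 0 and limma-trend on FPKM 1 with either pseudocount. The 1267 are not particular to this grouping. In splits tried after the data were seen, flox 1, flox 2 and LKO 2 against the rest gave 1682 genes under that unadjusted p. The other splits that match neither label gave 184 to 593.

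Of 37 lists tested with the genotype field, 15 passed the camera threshold, 6 higher and 9 lower in the libraries labelled LKO, and 0 passed with an estimated correlation or by fry. Of 31 cell cycle genes, 29 were below 0 and 0 passed over all genes, with 1 lower when adjusted over the list alone. The median was -0.85 (camera adjusted p = 2.15e-11, adjusted p = 0.791 with an estimated correlation). Mki67 and Top2a (log2 fold change -1.14), a topoisomerase of dividing cells, led it. Of 33 fibrosis and stellate cell activation genes, 32 were below 0 and 0 passed, over all genes or adjusted over the list alone. Their median was -0.97 (camera adjusted p = 7.13e-08, adjusted p = 0.846 with an estimated correlation), and the matrix proteoglycan genes Lum and Dcn had log2 fold changes of -2.15 and -0.76. Of 16 cholangiocyte and ductular markers 0 passed, over all genes or adjusted over the list alone, with a median of -1.48 (camera adjusted p = 1.95e-05, adjusted p = 0.846 with an estimated correlation). Cldn4 and Epcam, epithelial junction and adhesion genes, had log2 fold changes of -2.65 and -1.71. Lipid-associated macrophage markers (median -0.95, 0 of 17 passed, over all genes or adjusted over the list alone) had a camera adjusted p of 0.000119, and adjusted p = 0.846 with an estimated correlation. MHC class II genes (median -0.97, 0 of 9 passed, over all genes or adjusted over the list alone) had a camera adjusted p of 0.000277, and adjusted p = 0.846 with an estimated correlation. Of 23 unfolded protein and integrated stress response genes, 0 passed over all genes and 1 was higher when adjusted over the list alone, with a median of 0.22 (camera adjusted p = 4.56e-05, adjusted p = 0.791 with an estimated correlation). The chaperone genes Hyou1 and Calr had log2 fold changes of 0.71 and 0.55. Leaving out 1 library changed some of these medians by over 1.5 times: without flox 1 they were -0.454 for fibrosis, -0.818 for cholangiocyte and -0.552 for lipid-associated macrophage genes, and without LKO 1 the MHC class II median was -1.73. By the titles the unfolded protein and integrated stress response list had a median of -0.06 and did not pass (camera adjusted p = 0.542), from -0.128 to 0.045 without 1 library.

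In the 4 libraries whose labels agree, 6 of 34 fibrosis genes, 4 of 17 lipid-associated macrophage markers and 6 of 10 MHC class II genes fell in LKO, and 4 Cyp2c genes rose. Col1a1 (ENSMUSG00000001506, chromosome 11, 94827050 to 94843868, plus strand), a chain of type I collagen, fell from 174.7 ± 36.6 CPM in flox to 17.8 ± 1.16 CPM in LKO (SD, n = 2 each). Its log2 fold change was -3.29 (SE 0.21, edgeR adjusted p = 0.0159). Trem2, a lipid-sensing receptor of macrophages, fell from 37.5 ± 18.0 to 3.89 ± 1.58 CPM (log2 fold change -3.27, SE 0.43, edgeR adjusted p = 0.0455). H2-Aa, an MHC class II chain, fell from 226 ± 51.0 to 45.2 ± 4.13 CPM (log2 fold change -2.32, SE 0.21, edgeR adjusted p = 0.0195). Cyp2c37, a cytochrome P450, rose from 109 ± 40.3 to 915 ± 222 CPM (log2 fold change 3.08, SE 0.33, edgeR adjusted p = 0.0281). The library labelled flox 3 had 24.2 CPM of Col1a1, 4.54 of Trem2, 92.1 of H2-Aa and 550 of Cyp2c37, and the library labelled LKO 1 had 54.5, 17.1, 163 and 314.

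Of 14625 genes, edgeR called 91 in these libraries, 19 higher and 72 lower in LKO. The other higher genes named by the rule were Mup16 (log2 fold change 7.42), Sult2a7 (5.33), Cyp2c69 (4.48), the scavenger receptor gene Cd163 (4.21), Cnmd (3.38), Cyp2c40 (2.43), Slc22a26 (2.24), the sodium channel gene Scnn1a (2.14) and Rdh16f2 (1.76). Their SEs were 0.17 to 0.79 and their edgeR adjusted p 0.0176 to 0.0429. Mup16, Sult2a7 and the Cyp2c genes share reads with near-identical copies and are uncertain. The other largest falls named by the rule were in Pls1 (-5.61), encoding the actin bundler plastin 1, H2-M2 (-4.70), Gipc2 (-4.43), Fam83a (-4.00), the T cell gene Themis (-3.87), Mup20 (-3.54), Ccdc120 (-3.37) and the oxysterol-binding protein gene Osbpl3 (-3.35). Their SEs were 0.28 to 0.39 and their edgeR adjusted p 0.0155 to 0.0236. Mup20 is a member of a multigene family and uncertain. LKO 2 held transcripts of adrenal gland and fat, and LKO 3 held 10.3% as much over adrenal cortex markers: Cyp21a1, the adrenal steroid 21-hydroxylase, chosen after its value was seen, was at 694.9 CPM in LKO 2, 71.3 in LKO 3 and at most 0.533 in the others. None of the 91 genes (0) was among the 828 genes at least 8 times higher in LKO 2 than in flox 1 to 3 and LKO 1. The 72 lower genes could not have been among them, so the 0 bears on the 19 higher genes only. A gene much higher in LKO 2 than in LKO 3 is also hard to call with n = 2. No count floor was set for the 828, and 50 genes were at least 10 times higher in LKO 2 with 100 counts or more.

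**Figure D2:**
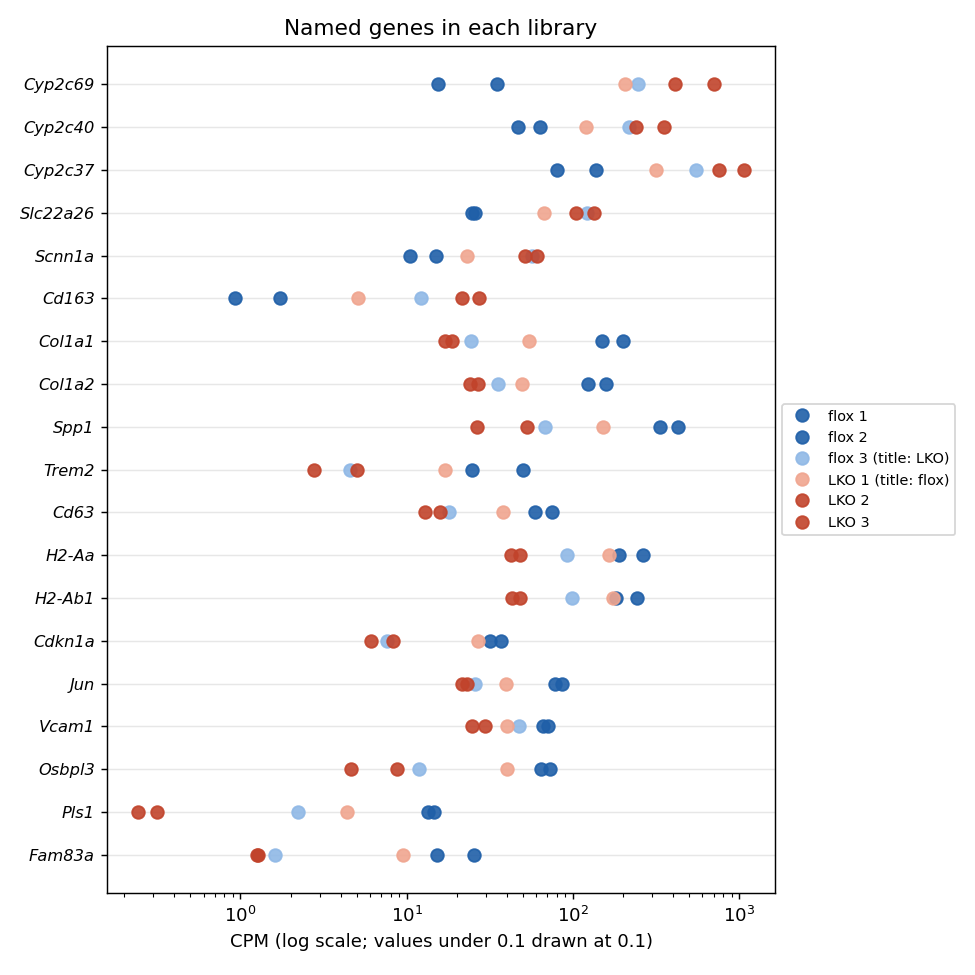
CPM (horizontal log axis) of named genes in each library, 1 point per library and gene, with lighter points for the 2 libraries whose title and genotype field conflict. Col1a1 was at 200.7 and 148.8 CPM in flox 1 and 2, at 18.6 and 17.0 in LKO 2 and 3, and at 24.2 and 54.5 in the libraries labelled flox 3 and LKO 1.

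Among the lists, 19 of 38 passed camera in the 4 agreeing libraries, 7 higher and 12 lower in LKO, and 0 passed with an estimated correlation or by fry. Of 34 fibrosis and stellate cell activation genes, 6 fell, 0 rose and 28 did not pass, with 25 lower when adjusted over the list alone. Col1a1 and Col1a2 (-2.47) were among the 6, and the list had a median of -1.29 (camera adjusted p = 1.67e-16, adjusted p = 0.481 with an estimated correlation). Of 17 lipid-associated macrophage markers 4 fell, among them Trem2, Cd63 (-2.21) and Spp1 (-3.27), with 13 lower when adjusted over the list alone. The median was -1.43 (camera adjusted p = 2.78e-12, adjusted p = 0.481 with an estimated correlation). Of 10 MHC class II presentation genes 6 fell, among them H2-Aa and H2-Ab1 (-2.22), with 7 lower when adjusted over the list alone (median -2.02, camera adjusted p = 2.16e-10, adjusted p = 0.481 with an estimated correlation). Of 17 cholangiocyte and ductular markers Spp1 alone fell, with 13 lower when adjusted over the list alone, and Ehf had a log2 fold change of -2.47 that did not pass (edgeR adjusted p = 0.0575). That list had a median of -2.36 (camera adjusted p = 2.16e-10, adjusted p = 0.481 with an estimated correlation). Of 31 cell cycle genes Cdkn1a (-2.25), an inhibitor of the cycle, fell, and 2 were lower when adjusted over the list alone (median -0.94, camera adjusted p = 2.04e-08, adjusted p = 0.481 with an estimated correlation). Of 23 immediate early and heat shock genes the transcription factor gene Jun (-1.87) fell, and 9 were lower when adjusted over the list alone, while Klf6 (-1.14) did not pass (edgeR adjusted p = 0.0575). The list had a median of -0.50 (camera adjusted p = 0.00022, adjusted p = 0.481 with an estimated correlation).

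Of 24 female-predominant liver genes, 3 rose, among them Cyp2c69 and Cyp2c40, and 0 fell. Adjusted over the list alone, 13 were higher and 2 lower, and the median was 2.00 (camera adjusted p = 4.62e-06, adjusted p = 0.481 with an estimated correlation), or 1.25 without flox 1 and 1.19 without LKO 3. The male-predominant list did not go the other way: 1 of 21 fell and 0 rose, with 6 higher and 4 lower when adjusted over the list alone. Its median was 0.46 and it did not pass (camera adjusted p = 0.199). Of 19 xenobiotic P450 and CAR/PXR target genes, Cyp2c37 and Cyp2c50 (1.45) rose and 0 fell, with 9 higher and 1 lower when adjusted over the list alone (median 0.77, camera adjusted p = 1.74e-05, adjusted p = 0.481 with an estimated correlation). Of 20 chemokine and inflammatory cytokine genes the adhesion molecule gene Vcam1 (-1.33) fell, with 1 higher and 3 lower when adjusted over the list alone. Cxcl5 was at 2.53 and 0.928 CPM in flox 1 and 2 and at 0 in LKO 2 and 3, and did not pass (edgeR adjusted p = 0.0982). This list had a median of -0.65 (camera adjusted p = 0.00122, adjusted p = 0.674 with an estimated correlation), and -0.305 without flox 1 and -1.11 without flox 2. Kupffer cell markers (median 0.20, with Cd163 higher of 14) and sinusoidal endothelial markers (median 0.22, 0 of 16 passed) did not pass camera (adjusted p = 0.301 and 0.0549). The Kupffer cell median was -0.188 without LKO 2 and the endothelial median 0.0319 without flox 1. Of 5 adipocyte markers 0 passed over all genes and 4 were higher when adjusted over the list alone, with a median of 8.81 (camera adjusted p = 0.0016, adjusted p = 0.572 with an estimated correlation). The list is counted among the 7 higher ones. Its member Plin1, chosen after its value was seen, was at 26.2 CPM in LKO 2, 3.23 in LKO 3 and at most 0.13 in the other libraries. Its rise cannot be told apart from the fat transcripts held by LKO 2.

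Glucose and fatty acid synthesis genes did not pass in these libraries. Of 23 glycolysis and hexokinase genes 0 passed over all genes or adjusted over the list alone (median -0.11, camera adjusted p = 0.0842, and -0.244 without LKO 2). Pfkfb3 had a log2 fold change of -0.37 (SE 0.15, edgeR adjusted p = 0.295). Hk1, Hk2 and Hk3 had log2 fold changes of -0.07 (SE 0.35), -0.45 (SE 0.39) and -0.07 (SE 0.20), with edgeR adjusted p of 0.94, 0.62 and 0.896. Of 21 fatty acid synthesis genes 0 passed over all genes or adjusted over the list alone (median -0.10, camera adjusted p = 0.461, and -0.378 without flox 1 and 0.349 without flox 2). The lipogenic transcription factor genes Mlxipl and Srebf1 had log2 fold changes of 0.77 and 0.65 (edgeR adjusted p = 0.168 and 0.292).

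The count of 91 became 0 without flox 1, 50 without flox 2, 759 without LKO 2 and 629 without LKO 3, fits in which a lone library is assumed to vary like the other group. It was 733 by DESeq2, 44 by limma-voom, 57 with upper-quartile factors and 1108 with no filter on low counts.

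**Figure D3:**
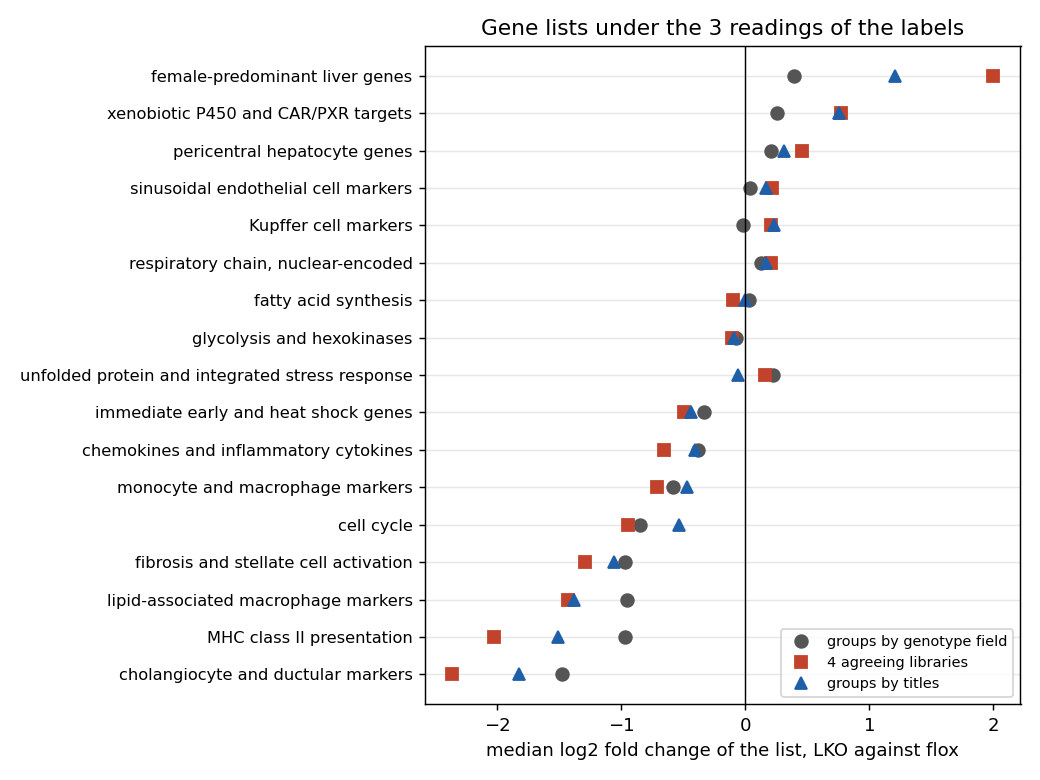
Median log2 fold change (horizontal axis, LKO against flox) of 17 gene lists under the 3 readings of the labels. The fibrosis and stellate cell activation list had medians of -0.97 by the genotype field, -1.29 in the 4 agreeing libraries and -1.06 by the titles.

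With the groups the titles name, 43 genes fell, among them Cdkn1a, Trem2 and Cd63, and 8 rose, among them Scnn1a and Fcna. Cdkn1a (ENSMUSG00000023067, chromosome 17, 29309950 to 29319701, plus strand), the p21 inhibitor of cyclin-dependent kinases, fell from 31.8 ± 5.06 to 7.35 ± 1.14 CPM (SD, n = 3 each). Its log2 fold change was -2.12 (SE 0.17, edgeR adjusted p = 0.018). Trem2 (log2 fold change -2.91) and Cd63 (-1.88), a lysosomal tetraspanin gene, fell (edgeR adjusted p = 0.0438 and 0.0332). Fam83a (-3.60), Ubd (-3.15), Ccdc120 (-3.03), Osbpl3 (-2.82), the growth factor gene Nrg1 (-2.76), Ly6d (-2.32) and Uap1l1 (-2.02) also fell. Sprr1a fell too and was at 2.07, 5.57 and 3.49 CPM in flox 1, flox 2 and LKO 1 and at most 0.0649 in the rest. Mup16 (7.31), Cnmd (2.90), Cyp3a44 (2.72), Scnn1a (1.796), the ficolin gene Fcna (1.28), the carboxylesterase gene Ces3b (1.17) and Gas1 (0.71) rose, and Mup16 and Cyp3a44 are uncertain because near-identical copies share reads. Cyp4a10 (0.98) and Slc43a1 (1.35) did not pass (edgeR adjusted p = 0.0501 and 0.0626).

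In this reading edgeR called 51 of 14310 genes, 8 higher and 43 lower. With the 91 genes above 26 were shared, and these comparisons share 4 libraries. Of 37 lists 24 passed camera, 9 higher and 15 lower, and 0 with an estimated correlation or by fry. By the mixed test of fry 12 passed, against 0 by the genotype field and 0 in the 4 agreeing libraries. Lowest among the 12 were mitochondrially encoded respiratory chain genes (fry mixed adjusted p = 0.000944) and lysosome genes (0.00476). Acute phase (0.00727), Kupffer cell (0.0126) and male-predominant genes (0.0126) came next. Lipid-associated macrophage, MHC class II, female-predominant and NRF2 genes passed with higher values (fry mixed adjusted p 0.0301 to 0.0425). Fibrosis genes did not pass the mixed test (0.0732). Lipid-associated macrophage markers fell in 2 of 17 and in 14 when adjusted over the list alone (median -1.38, camera adjusted p = 1.66e-12, adjusted p = 0.382 with an estimated correlation), or -0.838 without flox 1. Fibrosis and stellate cell activation genes passed in 0 of 33, with 24 lower when adjusted over the list alone (median -1.06, camera adjusted p = 2.4e-13, adjusted p = 0.432 with an estimated correlation). Its members Col1a1 and Timp1 had log2 fold changes of -2.76 and -2.59 and did not pass (edgeR adjusted p = 0.0501 and 0.054). MHC class II genes passed in 0 of 9, with 7 lower when adjusted over the list alone (median -1.51, camera adjusted p = 2.13e-09, adjusted p = 0.382 with an estimated correlation). Female-predominant liver genes had 1 higher of 25, Cyp3a44, and 9 higher and 1 lower when adjusted over the list alone (median 1.21, camera adjusted p = 1.04e-06, adjusted p = 0.382 with an estimated correlation), or 2.22 without LKO 1. Of 20 NRF2 and glutathione genes 0 passed over all genes and 6 were lower when adjusted over the list alone (median -0.28, camera adjusted p = 4.32e-05, adjusted p = 0.382 with an estimated correlation, median -0.183 without LKO 2), and Gstp1 and Ephx1 had log2 fold changes of -0.77 and -0.65.

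The count of 51 became 20 without flox 1, 0 without flox 2, 29 without flox 3, 238 without LKO 1, 4 without LKO 2 and 1 without LKO 3. It was 629 by DESeq2, 24 by limma-voom, 25 with a mean of at least 1 CPM, 247 with no filter and 30 on log2(FPKM + 1).

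**Figure D4:**
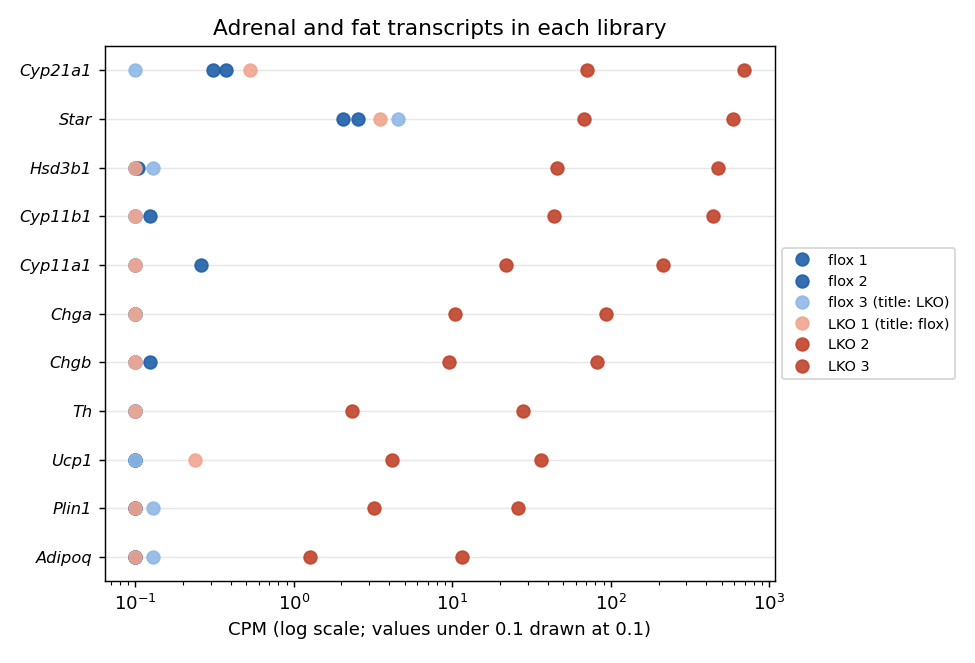
CPM (horizontal log axis, values under 0.1 drawn at 0.1) of adrenal and fat transcripts, chosen after their values were seen, in each library, 1 point per library and gene. Cyp21a1 was at 694.9 CPM in LKO 2, 71.3 in LKO 3 and at most 0.533 in the other libraries.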

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

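Fits on the 4 agreeing libraries and on the title groups, beyond their main values, and the fit without the genes high in LKO 2 were chosen after the data were seen. No paired analysis was possible because the replicate numbers follow accession order and pair no samples. By the genotype field, edgeR's count of 0 genes became 35 with DESeq2, 1 on log2(FPKM + 1), 1 on log2(FPKM + 0.1), 91 in the 4 agreeing libraries and 51 by the titles. It was 0 without any 1 library. The 15 lists became 24 by the titles, 0 with an estimated correlation and 0 by fry, and 9 to 21 without 1 library (9 without flox 1 and 9 without LKO 3). In the 4 agreeing libraries the 91 genes became 57 with upper-quartile factors, 1108 with no filter, 733 with DESeq2, 44 with limma-voom and 346 at an adjusted p under 0.10. They were 0 to 759 without 1 library (0 without flox 1, 50 without flox 2, 759 without LKO 2 and 629 without LKO 3). The 19 lists became 0 with an estimated correlation, 0 by fry and 20 to 29 without 1 library. By the titles the 51 genes became 247 with no filter, 25 with a mean of at least 1 CPM, 629 with DESeq2, 24 with limma-voom, 30 on log2(FPKM + 1) and 181 at an adjusted p under 0.10. They were 0 to 238 without 1 library (0 without flox 2, 238 without LKO 1). The 24 lists became 0 with an estimated correlation, 0 by fry and 12 by its mixed test. Without the 828 genes high in LKO 2, the counts were 0, 133 and 59. Hkdc1 stayed lower in LKO in every setting, from -3.05 to -1.22 by the genotype field without 1 library. It passed in the 4 agreeing libraries with no filter (-3.59, edgeR adjusted p = 0.00575), with DESeq2 (-3.64, adjusted p = 0.0187) and without LKO 3 (-4.86, range from -4.86 to -2.90, edgeR adjusted p 0.0307). By the titles it passed with DESeq2 (-3.57, adjusted p = 0.00602) and without LKO 1 (-3.88, range from -4.44 to -2.87, edgeR adjusted p = 0.0476). Over all its alternatives in the 3 readings the adjusted p was 0.00575 to 0.906. Values without a called direction that changed sign were Hk1 (without 1 library from -0.35 to 0.20 by the genotype field, from -0.50 to 0.35 in the 4 libraries and from -0.29 to 0.26 by the titles). Hk2 in the 4 libraries ranged from -1.19 to 0.036 and Hk3 from -0.25 to 0.11. By the titles Hk3 was 0.054, and -0.057 with library size alone, -0.033 on log2(FPKM + 1), -0.036 on log2(FPKM + 0.1) and from -0.037 to 0.216 without 1 library. Calr was -0.064 by the titles, and the unfolded protein list had a signed -log10 camera p of -0.29 there. The cause of these changes was not tested, except that the fits without a library have fewer samples. With 16166515 to 17366295 counts a library, Hkdc1 at 1 count in flox 3 and LKO 2 and 4 in LKO 3 was near the floor of 3 counts. Its 10 counts in LKO 1, 22 in flox 2 and 49 in flox 1 lay above that floor.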

Other observations

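Every test in this part was chosen after the results were seen. Of the 91 genes called by edgeR in the 4 agreeing libraries, the following were chosen after their values were seen. They were not tested as a group. Anxa2 fell by 1.798, Anxa5 by 1.69, Lgals1 by 1.46 and S100a11 by 1.86 on the log2 scale (edgeR adjusted p 0.0201 to 0.0432). Clec7a, a fungal glucan receptor of myeloid cells, fell by 2.59, and Prlr, the prolactin receptor gene, rose (1.48). Unc5b, which lies on the same chromosome as Hkdc1, fell from 59.3 ± 3.04 to 12.1 ± 0.864 CPM (SD, n = 2 each, log2 fold change -2.29, edgeR adjusted p = 0.0155). These counts rest on the same 4 libraries, and edgeR called 0 genes without flox 1.

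Of the KEGG pathways named in the deposited table, steroid hormone biosynthesis had the lowest camera p in the 4 agreeing libraries, with 3 of 71 genes higher and 0 lower (median 0.65, camera adjusted p = 4.54e-08, adjusted p = 0.81 with an estimated correlation). Of these 71 genes 6 were among the 828 high in LKO 2, which held adrenal transcripts, and without the 828 the pathway had 5 of 65 genes higher and 0 lower (median 0.517, camera adjusted p = 5.9e-07, adjusted p = 0.817 with an estimated correlation). ECM-receptor interaction had 5 of 69 genes lower (median -0.45, camera adjusted p = 1.42e-05, adjusted p = 0.81 with an estimated correlation). Phagosome had 7 of 135 lower (median -0.23, camera adjusted p = 7.86e-05, adjusted p = 0.81 with an estimated correlation). By the genotype field, proteasome genes had the lowest p, with 0 of 45 passing (median 0.16, camera adjusted p = 4.44e-07, adjusted p = 0.891 with an estimated correlation). Library flox 1 stood apart in H19, an imprinted noncoding RNA, at 59.8 CPM against 2.11 to 14.2 in the rest, and in Ankrd37 at 9.52 against 0.592 to 2.03. The values assigned to single Mup genes differed between libraries: Mup12 was at 936 CPM in LKO 2 and 0.444 in LKO 3, and Mup17 at 149 and 379. The sum of the 22 Mup genes was 3832 and 2391 CPM there and 1247 to 1724 in the others. Whether expression or the assignment of reads shared by Mup copies differed cannot be told from these values.

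Of the 2 libraries with conflicting labels, flox 3 had 1 count of Hkdc1, as LKO 2 had, and LKO 1 had 10, a difference beyond counting error (exact binomial p = 0.01213). Flox 3 lay under flox 2 (exact binomial p = 2.72e-06) and was not told apart from LKO 3 (exact binomial p = 0.375). LKO 1 lay between the groups (exact binomial p = 0.0216 against flox 2 and 0.181 against LKO 3). The 91 genes called without these 2 libraries were placed at 0 at the flox mean and 1 at the LKO mean. Over them, flox 3 had a median position of 0.811 (interquartile range 0.675 to 0.898) and was nearer LKO for 80, so a wrong genotype field is a candidate explanation. LKO 1 had a median of 0.379 (interquartile range 0.247 to 0.556) and was nearer flox for 59. By the chi-square per gene, LKO 1 was nearest flox 2 (17.3), then flox 3 (29.55), LKO 3 (35.14), LKO 2 (41.9) and flox 1 (46.76). That order does not place it in either group, so whether its field is wrong cannot be told apart from a knockout with intermediate values. Other differences between mice were not tested.

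Of the 10 splits of the 6 libraries into 3 and 3, 1 gave as many genes as the 51 of the titles (highest other 0). All 10 gave at least the 0 of the genotype field (highest other 51), which any split must reach, so that count carries no information. For lists, 7 gave at least the 15 of the genotype field (highest other 24) and 1 the 24 of the titles (highest other 23). With 10 splits, a share under 0.05 cannot be reached.

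LKO 2 held adrenal and fat transcripts: 9 of 10 adrenal cortex markers, 7 of 10 adrenal medulla markers and 3 of 8 brown fat markers were at least 10 times higher there than in flox 1 to 3 and LKO 1. Cyp21a1 was at 694.9 CPM, Chga at 92.8 and Ucp1 at 36.3. Star, a steroidogenic transport gene that flox 1 to 3 and LKO 1 hold at up to 4.54 CPM, was at 590. By the same measure and a minimum count, 0 of 8 kidney markers in the table, 0 of 5 ovary and 0 of 6 gut epithelium markers were higher, which argues against kidney. Ovary is less clear: its marker Foxl2 had 13 counts in LKO 2, 2 in LKO 3 and 0 in flox 1 to 3 and LKO 1, too few to judge. A piece of adrenal gland with surrounding fat taken with the liver is a candidate source in LKO 2. LKO 3 had 10.3% of the LKO 2 level over cortex, 11.1% over medulla and 11.5% over brown fat markers, and of the genes with at least 100 counts in LKO 2 only Mup12, Mup19 (2.94%) and D430041D05Rik (4.29%) were under 0.5 times the cortex share. Material of LKO 2 carried into LKO 3 would give such a share but would also bring Mup12 to 96.4 CPM in LKO 3, where it was at 0.444 (0.0474% of LKO 2), and since how reads shared by Mup copies were assigned is not known, carry-over and the same tissue mix taken with both livers both stay open, and no biological explanation was tested.

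The fall of matrix, lipid-associated macrophage and MHC class II genes in the 4 agreeing libraries was weighed against 3 technical explanations. A lower share of every cell type other than hepatocytes is argued against by the sinusoidal endothelial markers, with a median of 0.217 (interquartile range 0.0764 to 0.406) against -1.43 (interquartile range -3.14 to -0.974) for lipid-associated macrophage markers, and without flox 1 of 0.0319 (interquartile range -0.195 to 0.419), which still lies above the macrophage range there. Adrenal and fat tissue in LKO 2 and LKO 3 is argued against by flox 3, which lacks it and had a median position of 0.807 (interquartile range 0.614 to 0.896) on the 72 lower genes. Flox 3, titled LKO, shows only that values this low can occur without that tissue. If its genotype field is right, the same values would speak equally against loss of Hkdc1 as the cause. Without flox 1, flox 2 was the whole flox group, and the lipid-associated macrophage list had a median of -1.11 (interquartile range -2.49 to -0.817). That argues against flox 1 as the whole cause for this list, but rests on flox 2 alone. Stellate cell markers had a median of -0.283 with 0 of 12 passing, monocyte and macrophage markers had a median of -0.714 that became -0.254 (interquartile range -0.564 to 0.38) without flox 1, no biological explanation was tested, and differences between mice unrelated to genotype stay open with 2 libraries a group.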
